A study of Homo sapiens with 4 samples.

How the data were processed

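The data are small RNA libraries from RD cells, 1 from the input lysate and 3 from native pull-downs with biotinylated antisense probes (EVEN and ODD against exon 2 of HIPK3, and LacZ as control). Per the labels' protocols, RNA was extracted with phenol and chloroform, libraries were made with the QIAseq miRNA kit and sequenced single-end on an Illumina NovaSeq. The authors deposited raw counts per mature miRNA for the 4 libraries, with whole numbers and differing totals. The authors also deposited CPM, which equal each count divided by its library total and scaled to the unit to within 1.46e-11 CPM. Totals ran from 98950 reads in EVEN to 2987858 in the input, and the lowest total gives the widest counting intervals. The submitters' processing notes name the build GRCh38. Adapter trimming, the aligner, the miRNA annotation, the handling of reads that fit several miRNAs, the use of strand and the use of the kit's molecular identifiers are not given in the sources used here. If molecular identifiers were not collapsed, counts hold amplified copies and the counting intervals are too narrow.

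Each library is its own group by its title, with 1 biological replicate per the series' design text, so no test across replicates exists for a comparison of 2 groups. For each miRNA the log2 ratio of (count + 0.5) over the library total of miRNA counts was computed. A miRNA was tested in a comparison when it had at least 20 reads in at least 1 of the 2 libraries, and was called higher or lower at 2-fold. Folds are ratios of the shares of reads without the 0.5, with a 95% exact conditional Clopper-Pearson interval. Where a library had 0 reads, the fold is a bound against a floor of 3 counts. Ranks used the ratio with 0.5 added, so a miRNA at 0 reads can rank past measured ones that its bound does not exceed. Joint results needed the count minimum in each comparison involved. A ratio of shares says nothing of absolute amounts: when some miRNAs take a larger share, the others fall.

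The overlap of the 2 probe sets against the shared LacZ library was set beside n1 × n2 / N and beside 1000 simulations in which EVEN, ODD and LacZ reads were Poisson draws from 1 profile at their own depths. These simulations hold counting noise only. The 14 miRNA lists, the naming rule and most alternatives were fixed before the data were examined; the circHIPK3 partner names were recalled from general knowledge, with the usual guide arm chosen. A list with at least 3 tested members was described by the percentile of its median among 10000 random lists matched on 5 bins of mean expression.

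The text names miRNAs by a rule: the 10 highest and 10 lowest past 2-fold in each probe set against LacZ and in both sets together, the 5 highest and 5 lowest in the other comparisons, the 10 most abundant of each library, 4 of each list (the 2 most abundant and the 2 with the largest ratio) and each measured member of the partner lists. Names outside it are marked as chosen later. Hairpin coordinates, host genes and sequences come from GENCODE release 29 on GRCh38, the build the submitters name. That reference holds no mature arms, so the planned count of seed sites in exon 2 was left out, and an arm was taken as the 5′ or 3′ part of the hairpin.

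Alternatives were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), totals without the 10 most abundant miRNAs, minimums of 1 and 100 reads, 5 added to each count, the deposited CPM with 1 CPM added, a 4-fold threshold, and a 2-fold threshold with a counting interval that excludes 1. For both probe sets together, edgeR's quasi-likelihood test and DESeq2 were also fitted with EVEN and ODD as 2 samples against LacZ, which treats different probe sets as replicates, and the summed reads of the 2 sets were used. Duplex energies were computed with RNAduplex of ViennaRNA 2.7.2. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

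The steps were tested on simulated data with 200 changed miRNAs. For EVEN against LacZ, 78.9% of 19 miRNAs changed 4-fold and 100% of 37 changed 8-fold were called, and 2.86% of 210 unchanged ones. For ODD against LacZ the shares were 100% of 37, 100% of 42 and 0.465% of 215. For the fit of 2 probe sets against LacZ, edgeR called 94.6% and DESeq2 78.4% of 37 miRNAs changed 4-fold. The EVEN and ODD simulations held counting noise only. In the simulation for the fit, libraries varied less than in the data, where edgeR gave a coefficient of variation of 0.618. These shares therefore do not give the power on the data. A single simulated list of 10, shifted by 1 SD, reached percentile 87.6. A single draw cannot show how well percentiles separate shifts of that size.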

Results

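Small RNAs recovered with probes against circHIPK3 were counted in RD cells. RD is an established human line of embryonal rhabdomyosarcoma, a tumour with features of skeletal muscle. CircHIPK3 is a circular RNA made of exon 2 of HIPK3, which lies on chromosome 11 at 33286413 to 33287511 of GRCh38 on the plus strand and is 1099 nt long. Cell lysate was incubated under native conditions with biotinylated antisense probes, which were captured on streptavidin beads. One pull-down used the EVEN probes and another the ODD probes, 2 separate sets against exon 2, and a control pull-down used probes against the bacterial LacZ mRNA. Together with the input, this gave 4 libraries in 4 groups, 1 library and 1 biological replicate per group. The recovery of circHIPK3 itself was not analysed here. Exon 2 is also an exon of the linear HIPK3 transcript, and the probe sequences were not used here. Capture of linear HIPK3 RNA is therefore not excluded.

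The libraries held 2987858 miRNA reads for the input, 98950 for EVEN, 426450 for ODD and 425395 for LacZ. Of the 2656 mature miRNAs listed, 1146, 439, 592 and 745 had at least 1 read in these libraries. A count of 0 allows up to 1.00 CPM (reads scaled to a common library size) in the input, 30.3 in EVEN, 7.03 in ODD and 7.05 in LacZ, so absence is least informative in the EVEN library. With 1 library per group, no difference given here has a replicate check, and the counting intervals and floors cover counting error only. They describe differences between libraries, not between conditions.

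The let-7 family, conserved miRNAs that restrain growth and are abundant in differentiated cells, took the largest share of every library among the 14 lists. Its 9 listed members took 24.0% of the input reads, 31.98% of LacZ, 37.7% of EVEN and 50.9% of ODD. let-7b-5p led both circHIPK3 pull-downs, with 14.2% of EVEN reads (95% exact binomial interval 13.96 to 14.39) and 17.1% of ODD reads (17.0002 to 17.23), against 5.89% in LacZ and 2.98% in the input. In the EVEN library miR-18a-5p, of the growth-promoting miR-17-92 cluster, was second with 10.0% of reads (9.82 to 10.2). In the ODD library miR-16-5p, which represses cell cycle genes, was second with 15.9% (15.75 to 15.97). miR-206, a skeletal muscle miRNA, was among the 10 most abundant in all 4 libraries, at 4.21% of the input, 5.90% of LacZ, 9.53% of EVEN and 3.27% of ODD. The 10 most abundant miRNAs took 44.1% of the input, 52.1% of LacZ, 63.9% of EVEN and 72.5% of ODD reads.

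**Figure D1:**
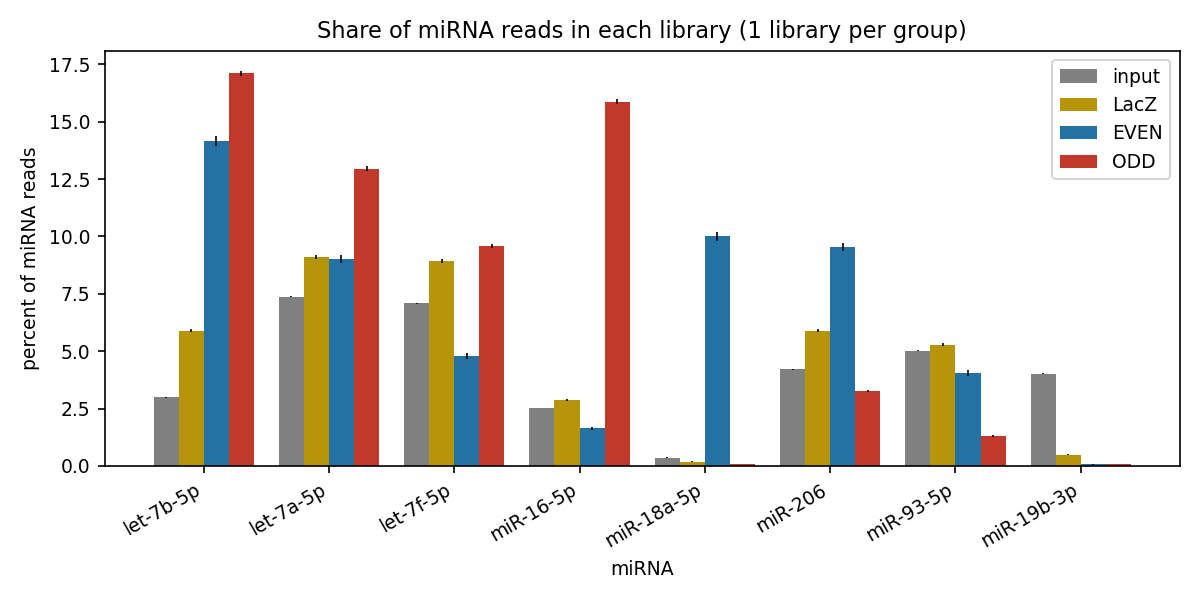
Percent of miRNA reads (y axis) taken by 8 abundant miRNAs (x axis) in the input, LacZ, EVEN and ODD libraries, 1 library each; error bars are 95% exact binomial intervals and cover counting error only. miR-16-5p stands at 15.9% in ODD alone and miR-18a-5p at 10.0% in EVEN alone, while let-7b-5p is at 14.2% and 17.1% in the 2 circHIPK3 pull-downs.

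The comparison of the EVEN probes with LacZ asks which miRNAs the EVEN probes recovered beyond what control probes retain. miR-18a-5p was 52.0-fold higher with EVEN probes (95% counting interval 48.4 to 55.9), with 9897 reads against 819 in the deeper LacZ library. miR-21-5p, a miRNA raised in many tumours, was 17.3-fold higher (15.8 to 18.9), miR-92b-5p 13.4-fold (10.8 to 16.8) and miR-489-3p 19.5-fold (10.0 to 41.6). The highest ratios belonged to rare miRNAs, miR-365b-5p at 124.7-fold (20.7 to 5092, from 29 and 1 reads) and miR-1914-5p at 81.7-fold (26.6 to 408, from 57 and 3 reads). let-7e-3p (22.6-fold), miR-193b-5p (6.53-fold), miR-188-3p (6.51-fold) and miR-432-5p (6.18-fold) completed the 10 highest. At the other end, let-7i-3p had 0 reads against 432 and was at least 33.5-fold lower, miR-449a, of a family that acts in ciliated epithelia, was 51.9-fold lower (17.7 to 253), and miR-1301-3p 28.2-fold lower (16.5 to 53.1).

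MIR18A lies in an exon of its host transcript MIR17HG on chromosome 13 at 91350751 to 91350821, plus strand. MIR21 lies on chromosome 17 at 59841266 to 59841337, plus strand, within an exon of VMP1. Among the other 7 of the 10 lowest with EVEN probes, all at 0 reads there, were miR-33a-5p (at least 7.37-fold lower), miR-29c-3p (at least 7.21-fold), miR-627-3p (at least 5.58-fold) and the muscle-derived miR-133a-5p (at least 4.26-fold). Their rank comes from the 0.5 added to each count, and these bounds do not place them below measured miRNAs such as miR-29b-3p, at 13.96-fold lower. Of 289 tested miRNAs, those with at least 20 reads in at least 1 of the 2 libraries, 28 were at least 2-fold higher with EVEN probes and 148 at least 2-fold lower. The median log2 ratio of all tested miRNAs was -1.06, and relative to it 76 were higher and 73 lower. The split was 43 higher and 107 lower with median-of-ratios size factors, and 44 and 107 with the 10 most abundant miRNAs left out of the totals.

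With the ODD probes a different set of miRNAs led. miR-509-3-5p was 196-fold higher than with LacZ probes (83.6 to 604, from 981 and 5 reads), miR-510-5p 56.7-fold (32.2 to 110.3) and miR-1250-5p 35.0-fold (21.7 to 60.5). miR-17-3p was 23.3-fold higher (20.3 to 26.9), with 4984 reads against 213. miR-16-5p, with 67640 reads against 12285, was 5.49-fold higher (5.39 to 5.60), and miR-24-3p 2.70-fold (2.61 to 2.79). miR-449a was again low, at 168-fold below LacZ (65.3 to 618), with miR-653-3p at 93.2-fold (25.4 to 776), miR-6820-5p at 85.7-fold (23.4 to 713) and let-7i-3p at 72.2-fold (32.9 to 198), while miR-4440 and miR-582-3p had 0 reads and were at least 11.7-fold and 11.4-fold lower.

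Other miRNAs among the 10 highest with ODD probes were miR-10a-5p, encoded in the HOXB cluster, at 166-fold (29.3 to 6579, from 166 and 1 reads), miR-6735-5p at 43.2-fold, miR-184 at 26.1-fold, miR-1237-3p at 25.1-fold and miR-493-5p at 23.2-fold. miR-550a-3p had 77 reads against 0 and was at least 25.6-fold higher. MIR509-3 (147259652 to 147259726) and MIR510 (147272335 to 147272408) lie near each other on the minus strand of chromosome X, outside any annotated host gene on that strand. MIR16-1 lies in an intron of DLEU2 on chromosome 13 at 50048973 to 50049061, minus strand, and MIR16-2 in an intron of SMC4 on chromosome 3 at 160404745 to 160404825, plus strand. Of 300 tested miRNAs, 39 were at least 2-fold higher with ODD probes and 211 at least 2-fold lower, with a median log2 ratio of -1.79. Relative to that median 77 were higher and 71 lower, and the split was 66 and 103 with TMM factors, 68 and 96 with median-of-ratios size factors and 55 and 160 with the 10 most abundant miRNAs left out of the totals.

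miRNAs that pass in both probe sets are those least tied to the sequence of one set. Of 284 miRNAs tested in both, 9 were at least 2-fold above LacZ with EVEN and with ODD probes: let-7b-5p, miR-21-5p, miR-92b-5p, miR-409-3p, miR-423-5p, miR-3184-3p, miR-877-5p, miR-3187-3p and miR-574-5p. All 284 had at least 20 LacZ reads, so miRNAs that passed only through EVEN or ODD were left out. Of the 28 higher with EVEN 23 remained, and of the 39 higher with ODD 23. miR-21-5p had the largest smaller fold, at 17.3-fold with EVEN and 7.66-fold (7.04 to 8.36) with ODD probes. let-7b-5p was 2.41-fold (2.36 to 2.46) and 2.90-fold (2.86 to 2.95) higher, and miR-423-5p 3.36-fold (3.15 to 3.58) and 3.12-fold (2.98 to 3.27). miR-574-5p, at 2.22-fold (1.66 to 2.95) and 2.06-fold (1.69 to 2.53), miR-92b-5p with ODD probes, at 2.42-fold (1.94 to 3.05), and miR-3187-3p and miR-409-3p, with 21 and 20 reads in EVEN, had counting intervals that reach below 2-fold. MIR423 and MIR3184 overlap on opposite strands of chromosome 17 (30117079 to 30117172 plus, 30117086 to 30117160 minus), and the use of strand in the counting is not given in the sources used here, so miR-423-5p and miR-3184-3p are not 2 independent results.

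Among the 132 miRNAs at least 2-fold below LacZ in both sets, let-7i-3p, miR-449a, miR-132-5p, miR-411-5p and miR-1301-3p were furthest down by the smaller of their folds. MIRLET7B lies in an exon of MIRLET7BHG on chromosome 22 at 46113686 to 46113768, plus strand, and MIR449A in an intron of CDC20B on chromosome 5 at 55170532 to 55170622, minus strand. The 9 higher miRNAs compare with 1.86 for independent lists of these sizes. They also compare with a mean of 0.008 (highest 1) in 1000 simulations of unchanged libraries that share 1 simulated LacZ library. The 132 lower ones compare with 110.0 and a simulated mean of 0.263. Across the 284 miRNAs, which are not independent replicates, the log2 ratios of the 2 sets had a Pearson correlation of 0.64 (simulated mean 0.30) and a covariance of 2.04 (simulated 0.029). The only LacZ library could not be split, so part of the excess may come from the shared control. The simulations hold counting noise only, so ordinary variation between libraries could also exceed them. With TMM factors 17 miRNAs were higher and 86 lower in both, and with median-of-ratios size factors 19 and 79.

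**Figure D2:**
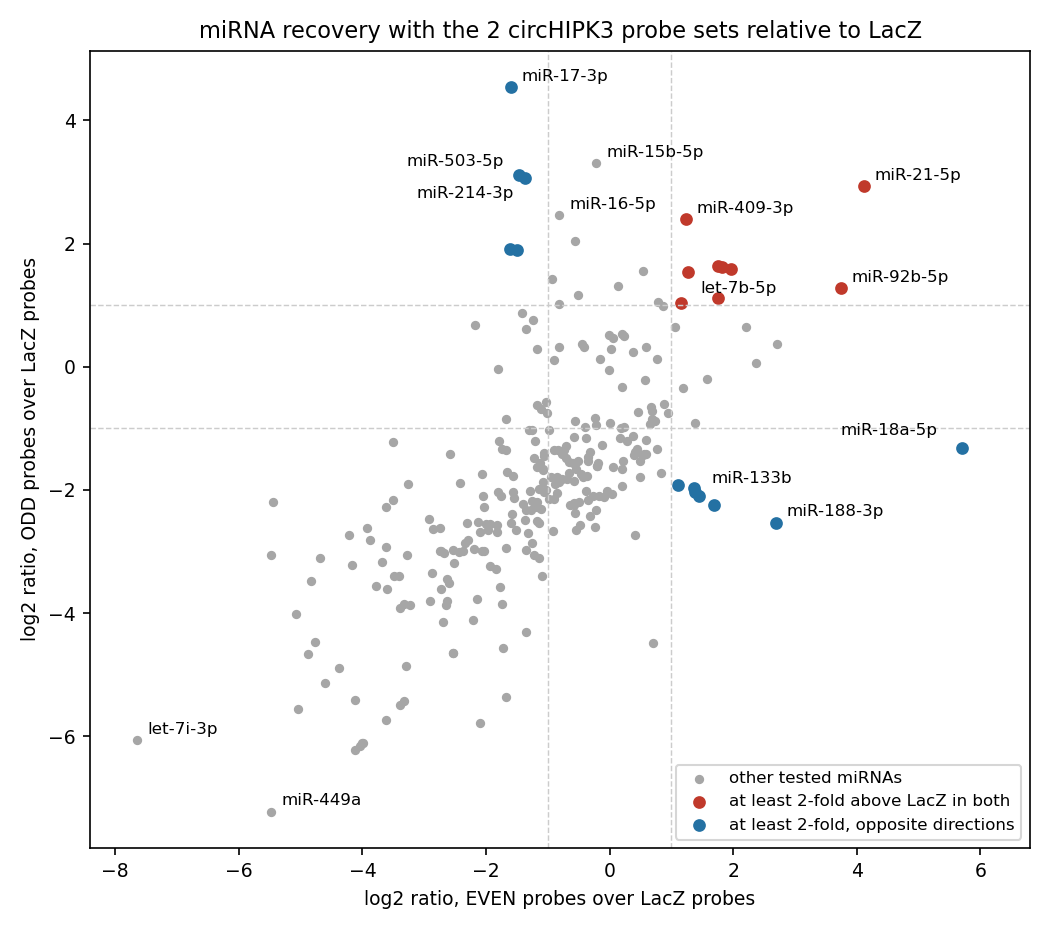
Log2 ratio over LacZ with EVEN probes (x axis) and ODD probes (y axis) for 284 miRNAs tested in both comparisons; each point is a miRNA, dashed lines mark a 2-fold difference, and 1 library stands behind each group. miR-21-5p lies farthest from 0 on both axes among the 9 miRNAs above 2-fold in both, miR-18a-5p lies at the right and miR-17-3p at the upper left; the labels of miR-15b-5p and miR-503-5p were chosen after their values were seen.

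The same 9 miRNAs were at least 2-fold above the input with both probe sets. miR-92b-5p had log2 ratios over the input of 7.38 with EVEN and 4.91 with ODD probes, miR-3184-3p of 4.75 and 4.36, miR-423-5p of 4.08 and 3.98, and let-7b-5p of 2.25 and 2.52. By library totals, 8 of the 9 were also above 0 in LacZ against the input, the exception being miR-21-5p with a log2 ratio of -0.63, and 5 were at least 2-fold higher there. For those 8, being 2-fold above LacZ already fixes being 2-fold above the input. Only miR-21-5p could have failed, so the input adds little to the result over LacZ. TMM factors lower every LacZ ratio to the input, taking the median of tested miRNAs from -0.44 to -1.04. That would also put miR-409-3p (0.21) and miR-574-5p (0.04) below 0, and miR-877-5p (1.11) and miR-3187-3p (1.09) under 2-fold. The count of 9 became 15 with TMM factors, 19 with median-of-ratios size factors and 1, miR-21-5p, at a 4-fold threshold.

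The 2 probe sets, which target the same exon, differed most in miR-1914-5p (246-fold higher with EVEN, 42.4 to 9871, from 57 and 1 reads), miR-18a-5p (130-fold, 116 to 145), miR-489-3p (71.8-fold, 23.2 to 360), miR-188-3p (40.2-fold, 17.4 to 114) and miR-509-3p (36.4-fold, 31.4 to 42.5). Higher with ODD probes were miR-510-5p, with 0 reads in EVEN (at least 52.7-fold), miR-1250-5p (139-fold, 24.8 to 5480), miR-509-3-5p (114-fold, 31.4 to 941), miR-17-3p (72.3-fold, 44.5 to 127) and miR-493-5p (at least 7.19-fold). In all, 203 miRNAs were tested, 77 at least 2-fold higher with EVEN and 37 with ODD probes. This balance turns with the scaling: TMM factors gave 20 and 64, median-of-ratios size factors 19 and 64, and a 4-fold threshold 22 and 25, while none of the miRNAs named here changed direction.

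Against the input, the EVEN library was highest in miR-92b-5p (168-fold, 128 to 223), miR-205-5p, an epithelial miRNA (151-fold, 50.6 to 607), and miR-509-3p (44.6-fold, 41.3 to 48.2), beside the rare miR-365b-5p and miR-1914-5p. The ODD library was highest in miR-205-5p (622-fold, 241 to 2295), miR-6735-5p (304-fold, 102 to 1491), miR-3177-3p (266-fold, 102 to 990) and miR-184 (173-fold, 108 to 295), beside the rare miR-1237-3p. For miR-205-5p the LacZ control was also far above the input, above EVEN and less than 2-fold below ODD. miR-33a-5p, miR-362-3p and miR-29c-3p, with 1955, 1900 and 1659 input reads, had 0 reads in EVEN and were at least 21.6-fold, 20.97-fold and 18.3-fold lower there. miR-660-3p, miR-873-5p and miR-376a-3p had 0 reads in ODD and were at least 16.3-fold, 15.9-fold and 14.4-fold lower. EVEN gave 85 higher and 242 lower of 464 tested, with a median log2 ratio of -1.06, and ODD 61 and 321 of 468, with a median of -2.19. With the 10 most abundant miRNAs left out of the totals the splits were 123 and 176 for EVEN and 102 and 243 for ODD, and adding 5 instead of 0.5 to each count gave 194 and 99 for EVEN. At a minimum of 1 read EVEN gave 677 and 242. Only 439 miRNAs had at least 1 EVEN read, so many of the 677 had 0 reads there. They were called higher through the added constant, which weighs more in EVEN, 30.2-fold shallower than the input. The split with 5 added is shaped by the constant too, so neither split shows a change of direction.

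LacZ probes have no target in these cells, so LacZ against the input shows what beads and control probes retained. miR-6820-5p was 1201-fold higher in LacZ (213 to 47713, from 171 and 1 reads), and miR-6125, miR-612, miR-203b-5p and miR-6862-5p had 24 to 37 reads against 0 in the input, at least 86.6-fold, 86.6-fold, 63.2-fold and 56.2-fold higher. miR-1-5p, miR-597-5p, miR-550a-3p, miR-505-3p and let-7f-2-3p had 0 reads in LacZ and 71, 71, 67, 58 and 55 in the input, at least 2.61-fold to 3.37-fold lower. Of 475 tested miRNAs 86 were at least 2-fold higher and 163 lower, with a median log2 ratio of -0.44. The split was 63 and 246 with TMM factors and 108 and 127 with the 10 most abundant miRNAs left out of the totals. It turned to 100 higher and 93 lower with 5 added to each count, and to 478 and 225 at a minimum of 1 read. In both settings the added constant weighs more in LacZ, 7.02-fold shallower than the input, so this turn is shaped by that constant.

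miRNAs reported elsewhere as partners of circHIPK3 did not stand above LacZ as a group. Of 9 named from an earlier reporter screen, 6 could be tested, and by library totals all 6 were at least 2-fold lower in both probe-set libraries. Of these, miR-654-3p with EVEN probes rests on 2 reads against 22, 2.56-fold lower (0.629 to 22.4), and its log2 ratio turned to 0.16 with 5 added to each count. That constant weighs more in the shallower EVEN library, so the turn is no sign of recovery. miR-29b-3p was 13.96-fold lower with EVEN (3.78 to 117) and 10.9-fold lower with ODD probes (5.90 to 22.5), and miR-29a-3p 7.04-fold (3.51 to 16.5) and 8.09-fold (5.52 to 12.2). The list's median log2 ratio was -2.05 with EVEN, at percentile 8.03 of 10000 random lists matched on expression, and -1.76 with ODD, at percentile 52.2, close to the median of all tested miRNAs and 0.03 when centred on it. miR-654-3p and miR-379-5p crossed 0 with ODD probes under median-of-ratios size factors. TMM factors raise every ODD ratio to LacZ, taking the median of all tested miRNAs from -1.79 to -0.50. That would put miR-379-5p (-1.36 by totals), miR-584-5p (-1.63) and miR-654-3p (-1.41) under 2-fold, so not all 6 would stay lower with ODD probes. Of the 3 untested members, miR-152-3p had 19 LacZ reads, and miR-124-3p and miR-193a-3p had 0 reads in all 3 pull-downs.

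Of 10 partners named by other reports, 7 were tested, with 1 higher and 4 lower with EVEN and 1 higher and 5 lower with ODD probes. miR-7-5p, an abundant miRNA known for its sponge CDR1as, was 7.49-fold lower with EVEN (6.67 to 8.44) and 13.99-fold lower with ODD probes (12.9 to 15.1), from 295, 681 and 9503 reads in EVEN, ODD and LacZ. miR-421 was 3.22-fold higher with EVEN (2.67 to 3.89) and 4.80-fold lower with ODD (3.59 to 6.52), but its ODD call was lost with TMM and median-of-ratios size factors. miR-107 was 2.94-fold higher with ODD (2.17 to 4.04) and 1.43-fold higher with EVEN (0.805 to 2.45), under the 2-fold threshold. The medians were -1.09 (percentile 41.1) and -2.25 (percentile 9.93).

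By library totals, the let-7 family had medians of 0.05 with EVEN (percentile 89.1) and 0.51 with ODD probes (percentile 96.6). Both lay inside the middle 95% of random lists (-1.54 to 0.59 and -2.54 to 0.65). EVEN against ODD its median was -0.41, at percentile 0.74, below the middle 95% (-0.27 to 1.28), again without replicates. Of 9 members, 3 were at least 2-fold higher with EVEN, let-7g-5p at 4.62-fold (4.36 to 4.90), let-7b-5p, and let-7e-5p at 2.07-fold (1.98 to 2.17), and miR-98-5p, named after its values were seen, was lower. With ODD probes let-7b-5p and let-7c-5p, the latter named after its values were seen, were higher and none was lower, and let-7a-5p was 1.42-fold above LacZ (1.40 to 1.44). TMM factors raise every ODD ratio to LacZ, taking the median of all tested miRNAs from -1.79 to -0.50. Every let-7 member lay above 0 with ODD probes by totals, so all 9, and the family median, would then pass 2-fold. Members differ by few bases and the authors' counting could split reads between them, so single members are uncertain.

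The skeletal muscle miRNAs differed between the sets. With EVEN probes 2 of 4 tested members were higher, miR-133a-3p at 2.17-fold (1.97 to 2.38) and miR-133b at 2.72-fold (1.74 to 4.19), miR-206 was 1.62-fold above LacZ (1.58 to 1.65) and miR-1-3p was 2.96-fold lower (2.52 to 3.50). With ODD probes miR-133b (4.40-fold, 2.38 to 8.75), miR-133a-3p (3.77-fold, 3.34 to 4.27) and miR-1-3p (3.44-fold, 3.14 to 3.77) were lower and miR-206 was 1.80-fold below LacZ (1.77 to 1.84), but its log2 ratio turned from -0.85 to 0.44 with TMM factors, 0.60 with median-of-ratios size factors and 0.94 when centred. The medians were 0.90 (percentile 97.1) and -1.85 (percentile 31.4), and EVEN against ODD the median was 2.29, at percentile 99.5, above the middle 95% of random lists (-1.07 to 1.64), also a difference between 2 libraries without replicates. The EVEN median turned to -0.33 at a minimum of 1 read. Centred on all tested miRNAs, the ODD median was -0.05 and miR-1-3p was at 0.01 with ODD probes.

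On the list of the miR-17-92 cluster and its paralogs, which does not include miR-17-3p, miR-18a-5p with EVEN probes was the only tested member at least 2-fold above LacZ. miR-19b-3p was 6.73-fold lower with EVEN (5.31 to 8.65) and 6.17-fold lower with ODD probes (5.49 to 6.94), and miR-20a-5p 2.58-fold (2.40 to 2.79) and 5.62-fold (5.32 to 5.95). Of 9 tested members 1 was higher and 4 lower with EVEN, and 8 were lower with ODD probes, with medians of -0.63 (percentile 61.5), which centring on all miRNAs turns to 0.43, and -2.02 (percentile 18.2). TMM factors raise every ODD ratio to LacZ and take the median of all tested miRNAs from -1.79 to -0.50. The ODD list median would then be under 2-fold, so fewer members would be called lower. miR-92a-3p turned from -0.99 to 0.30. In the imprinted 14q32 cluster 3 of 10 were higher and 4 lower with EVEN (median -0.19, percentile 96.7, and 0.07 with TMM factors), led by miR-432-5p and miR-134-5p (5.19-fold, 2.92 to 9.32), and 1 of 9 higher, miR-409-3p (5.34-fold, 3.74 to 7.80), and 7 lower with ODD probes (median -1.72, percentile 69.4, and 0.07 when centred). With TMM factors the 14q32 median with ODD probes would also be under 2-fold, and fewer than 7 would stay lower.

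**Figure D3:**
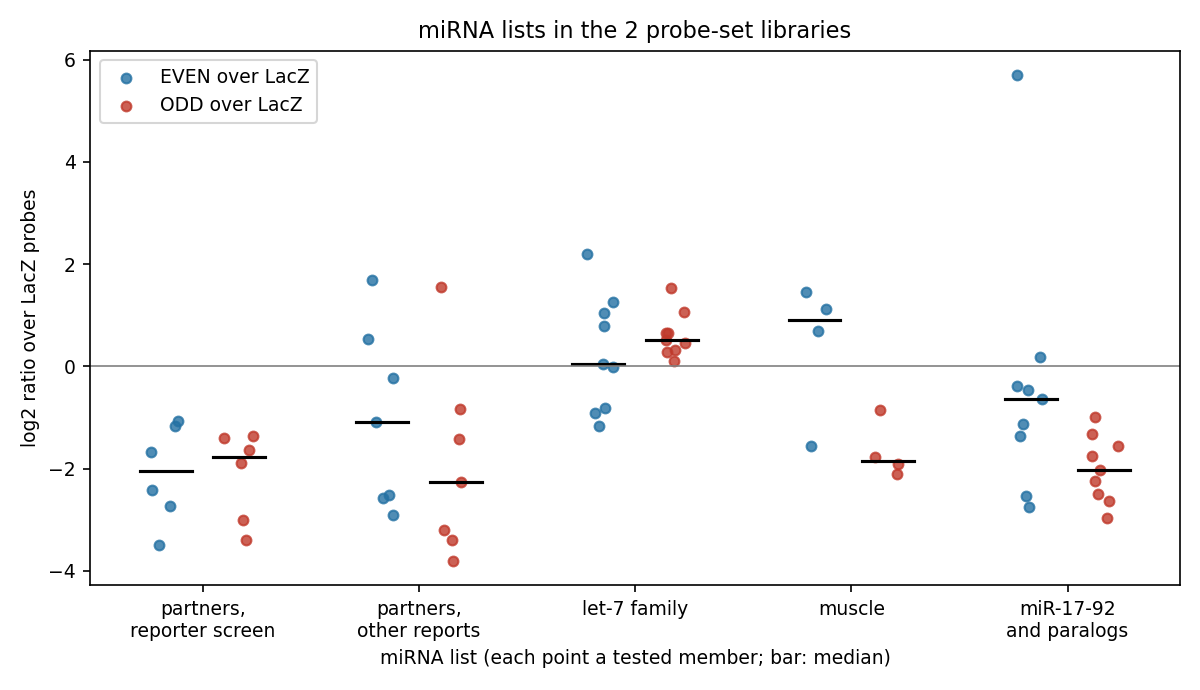
Log2 ratio over LacZ (y axis) of the tested members of 5 lists (x axis) with EVEN and ODD probes; each point is a miRNA, bars are list medians, and side shifts within a column only separate points. The 6 tested partners from the reporter screen all lie below -1 in both libraries, while let-7 members span -1.17 to 2.21 with EVEN and 0.10 to 1.54 with ODD probes.

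Neuronal miR-9-5p (3.82-fold lower with EVEN, 3.32 to 4.41, and 5.87-fold with ODD, 5.37 to 6.42), miR-9-3p and miR-128-3p were lower in both, with medians of -1.93 (percentile 9.09) and -2.55 (percentile 11.5). The endothelial pair miR-126-3p and miR-126-5p had medians of -2.12 and -2.58. Of the fibroblast and smooth muscle list, miR-199a-5p was 4.20-fold lower with EVEN (3.50 to 5.09) and 7.98-fold with ODD (7.04 to 9.07), whereas miR-214-3p was 2.62-fold lower with EVEN (1.91 to 3.68) and 8.41-fold higher with ODD (7.64 to 9.27). That list's medians over 3 members were -1.37 (percentile 35.8) and -2.38 (percentile 27.9).

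Epithelial miRNAs had medians of -1.24 (percentile 66.9) and -1.99 (percentile 66.1) over 3 members, with miR-205-5p 2.42-fold lower with EVEN (1.53 to 4.04) and 1.70-fold above LacZ with ODD probes (1.43 to 2.03). The list of miRNAs tied to DNA damage and p53 had medians of -1.09 (percentile 44.3) and -2.20 (percentile 26.7), with miR-24-3p the 1 member of 5 that was higher, with ODD probes, and miR-182-5p 3.65-fold lower there (3.13 to 4.28). The blood cell miR-486-5p was 1.58-fold above LacZ with EVEN (1.44 to 1.73) and 1.90-fold below with ODD probes (1.75 to 2.06), where its log2 ratio turned from -0.93 to 0.36 with TMM factors, 0.52 with median-of-ratios size factors and 0.87 when centred. Entries resembling other RNA classes had medians of -0.15 (percentile 82.2) and -0.60 (percentile 89.8) over 3 members, which turned to 0.11 and 0.69 with TMM factors, 1 of them, miR-4454, lower in both sets, though its log2 ratio with ODD probes turned to 0.06 with TMM factors. None of the 9 pluripotency miRNAs reached the count minimum.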

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

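All tests of explanations in this part were chosen only after the result was seen. Of 284 miRNAs tested against LacZ in both probe-set libraries, 12 were at least 2-fold away from LacZ in opposite directions, 7 of them higher with EVEN and 5 higher with ODD probes, where independent lists of these sizes would give 17.1 and 11.99. Without the 10 most abundant miRNAs in the totals 6 of the 7 and 4 of the 5 stayed in opposite directions, with TMM factors 1 (miR-188-3p) and 5, with median-of-ratios size factors 1 and 4, and centred on the median of the tested miRNAs 0 and 0, so the calls depend on the scaling. The differences of single miRNAs between the sets were not tested, since each group has 1 library.

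On the log2 scale, EVEN minus ODD, miR-18a-5p differed by 7.02, although its ODD ratio to LacZ moved from -1.32 to 0.13 with median-of-ratios size factors. miR-188-3p differed by 5.23, from 56 EVEN, 6 ODD and 37 LacZ reads. miR-421 differed by 3.94. The skeletal muscle miRNAs miR-133b and miR-133a-3p differed by 3.54 and 3.03. In the other direction miR-17-3p differed by -6.13 and miR-214-3p by -4.44. The other 5, named after their values were seen, were miR-1247-5p, miR-15a-5p, miR-503-5p, miR-7706 and miR-935.

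Of 8 tested miRNAs whose hairpin arm holds AGCAGC, 5 were at least 2-fold above LacZ with ODD and 0 with EVEN probes. The reference gives no mature arms, so AGCAGC may lie outside the mature miRNA in some of them. miRNAs whose names give no arm, such as miR-107, were not searched. The log2 ratios with ODD and EVEN probes were 2.46 and -0.82 for miR-16-5p and, named after their values were seen, 3.30 and -0.21 for miR-15b-5p, 3.12 and -1.47 for miR-503-5p, 1.92 and -1.62 for miR-15a-5p, 1.17 and -0.51 for miR-103a-3p, 0.68 and -2.17 for miR-424-5p, -1.61 and -0.20 for miR-191-5p and -2.07 and 0.04 for miR-589-5p. Pairing of AGCAGC, at the 5′ end of miR-16-5p, with circHIPK3 is argued against, since exon 2 holds 0 copies of GCTGCT, its complement, which leaves other modes of binding open and untested. Pairing with the antisense probes may be an explanation, but 7.5% of 1000 shuffled exon 2 sequences held as many copies of AGCAGC as the 2 in exon 2. The longer TAGCAGC, examined after that share was known, also had 2 copies in exon 2 and as many in 0.1% of shuffles, which makes it a hypothesis only, and the probe sequences were not used here. Over the 5 miRNAs with an arm tested in both sets, at least 4-fold higher with ODD and under 2-fold with EVEN probes, the energy of pairing with the probe strand against the circle strand lay at percentile 16.6 of random lists. A later run on 16 gave percentile 6.12 and was set aside after it was seen, since 11 of the 16 were under the read minimum for EVEN against LacZ and 4 of these were at least 2-fold higher with EVEN, so pairing with probes and other causes cannot be told apart with 1 library per set.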

How the results depend on the processing

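Centring on the median of the tested miRNAs and thinning every library to 98950 reads (median of 21 draws, a number raised from 20 so that medians are whole counts) were chosen after seeing the data; the other alternatives were chosen before. No paired analysis was possible because each group has 1 library. The planned count of seed sites was not run, since the reference holds no mature arms. The cause of a change was not tested except where the setting itself gives it: a higher or lower read minimum, thinning and a stricter threshold change how many miRNAs are tested or called. Of the counts and shares under an alternative, 101 stayed within 1.5 times or within their interval and 84 did not, and of the counts of opposite directions, an alternative added last, 10 and 10. Of the log2 ratios of named miRNAs, 948 stayed within their counting interval, 658 moved beyond it and 14, all at least 2-fold from 0 before, reversed. Of the 948, 270 came from the deposited CPM, which equal the counts over totals. With TMM factors 109 stayed and 160 moved, with median-of-ratios size factors 100 and 165, and centred 86 and 177. Of list medians, against a bootstrap interval, 79 stayed, 43 moved and 5 reversed. Among values under 2-fold, 98 of the log2 ratios and 14 of the list medians also changed sign. The 9 miRNAs higher in both sets were all kept with TMM factors, median-of-ratios size factors, totals without the 10 most abundant and centring. These settings raise every ratio to LacZ in both sets, so they could not remove any of the 9. A minimum of 1 read could not remove any either, and the deposited CPM, which kept all 9, equal the counts over totals. Of the settings that could remove members, a counting interval excluding 1 kept 9, 100 reads 7, 5 added to each count 8 and a 4-fold threshold 1. Thinned, 185 miRNAs were tested against LacZ with EVEN and 184 with ODD probes, 160.0 for EVEN against ODD, and 196, 194 and 193 for EVEN, ODD and LacZ against the input.

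With TMM factors, ODD against LacZ gave 66 higher and 103 lower, EVEN against ODD 20 and 64, LacZ against input 246 lower, both sets 17 higher and 86 lower, and both sets over LacZ and input 15. With median-of-ratios size factors, EVEN against LacZ gave 43 higher, ODD against LacZ 68 and 96 lower, EVEN against ODD 19 and 64, ODD against input 108 higher, both sets 19 and 79, and both sets over LacZ and input 19. Without the 10 most abundant miRNAs, EVEN against LacZ gave 44 higher, ODD against input 102, both sets 15, and both sets over LacZ and input 14.

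At 1 read, EVEN against LacZ gave 149 higher and 248 lower, ODD against LacZ 155 and 517, EVEN against ODD 260 and 83, EVEN against input 677 and 242, ODD against input 412 and 428, LacZ against input 478 and 225, both sets 36 and 213, and both sets over LacZ and input 32. At 100 reads, EVEN against LacZ gave 15 and 80, ODD against LacZ 108 lower, EVEN against ODD 39 higher, EVEN against input 43 higher, LacZ against input 45 and 106, and both sets 68 lower. With 5 added to each count, EVEN against LacZ gave 87 lower, EVEN against input 194 and 99, LacZ against input 100 and 93 and both sets 78 lower. With a counting interval excluding 1, EVEN against input gave 161 lower. At 1 read or with 5 added, the constant lifts ratios of a shallower library against a deeper one, so such splits partly reflect depth.

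At 4-fold, EVEN against LacZ gave 12 and 76, ODD against LacZ 20 and 137, EVEN against ODD 22 and 25, EVEN against input 46 and 153, LacZ against input 45 and 55, both sets 1 and 70, and both sets over LacZ and input 1. Centred, EVEN against LacZ gave 76 and 73, ODD against LacZ 77 and 71, EVEN against ODD 34 and 48, EVEN against input 135 and 148, ODD against input 156 and 148, both sets 35 and 56, and both sets over LacZ and input 32. Thinned, EVEN against LacZ gave 85 lower, ODD against LacZ 120.0 lower, EVEN against input 46 higher and 97 lower, ODD against input 119 lower, LacZ against input 40 higher and 59 lower, and both sets 74 lower.

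With both probe sets as 2 samples against LacZ, edgeR called 0 higher and 0 lower at an adjusted p of 0.05, with 28 at an unadjusted p under 0.05 and a smallest adjusted p of 0.420. DESeq2 called 3 higher and 2 lower, with 33 unadjusted, 88 given no adjusted p and a smallest adjusted p of 0.00184. The control has 1 library, so in both fits the spread comes only from the difference between the 2 probe sets, and LacZ is assumed to vary as they do. The summed reads of both sets gave 24 higher.

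These log2 values with ODD probes against LacZ, all at least 2-fold below 0 before, reversed. With median-of-ratios size factors, miR-18a-5p was at 0.13, miR-190b-5p at 0.036, miR-379-5p at 0.091, miR-4454 at 0.22 and miR-654-3p at 0.040. With TMM factors, miR-4454 was at 0.062. Centred, miR-1-3p was at 0.013, miR-18a-5p at 0.48, miR-190b-5p at 0.38, miR-379-5p at 0.44, miR-4454 at 0.57, miR-584-5p at 0.16 and miR-654-3p at 0.39, the reporter-screen partner list at 0.031 and the 14q32 list at 0.069. At 100 reads, the 14q32 list was at 2.40 and the epithelial list at 0.77, each from a single member left, miR-409-3p and miR-205-5p. The fibroblast and smooth muscle list was at 0.038 over the members left. With EVEN probes and 5 added to each count, miR-654-3p was at 0.16.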

Other observations

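Of the tests in this part, the medians without the 10 most abundant miRNAs and the relations with base composition were chosen before their results were seen; the tests of either as the whole cause, of retention by LacZ probes and of pairing with the probes were chosen only after. Arms of the miR-17 hairpin differed between the pull-downs, and the arms in this paragraph were picked after their values were seen. miR-17-5p had 82, 116 and 549 reads in EVEN, ODD and LacZ, and miR-17-3p from the same hairpin 16, 4984 and 213. miR-199a-3p and miR-199b-3p had 0 reads in all 4 libraries, although miR-199a-5p had 38657 input reads. In all, 12 arms had 0 reads in every library while their partner arm had at least 200 input reads, and 25% of them shared 16 nt with another name, against 17.3% of 196 arms above 0. The ratio of miR-3184-3p to miR-423-5p reads, from opposite strands of 1 locus, lay between 0.207 and 0.328 in the 4 libraries, a 1.59-fold range, while the miR-423-5p share of reads spanned 16.97-fold. Other such pairs ranged more widely, from 0.194 to 0.354 for miR-3184-5p to miR-423-3p and from 0.103 to 0.350 for miR-103b to miR-103a-3p.

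Most tested miRNAs lay below LacZ in both probe-set libraries, and no biological explanation was tested. The 284 miRNAs tested in both sets all had at least 20 LacZ reads, so the set was in effect chosen through LacZ. Such a choice favours ratios below LacZ, and how much it adds was not tested. The 10 most abundant miRNAs are argued against as the whole cause, since the other miRNAs kept a median log2 ratio of -0.66 with EVEN (95% bootstrap interval -0.80 to -0.46) and -1.14 with ODD probes (-1.34 to -0.95) with these 10 left out of the totals. Whether base composition is the whole cause depends on the scaling. By library totals, the third of hairpin arms richest in GC kept medians of -0.71 (-1.08 to -0.36) and -1.48 (-1.88 to -1.19). Median-of-ratios size factors raise every ratio to LacZ. They take the median of all tested miRNAs from -1.06 to -0.65 with EVEN and from -1.79 to -0.35 with ODD probes. That shift would carry both upper bounds past 0, so this test cannot decide. Either may account for part: the ODD median moved from -1.79 to -1.10 without the 10, and arm GC correlated with the ratio to LacZ across 259 miRNAs, which are not independent replicates, with a Spearman's rho of 0.30 for EVEN and 0.26 for ODD probes. Against the input the rho was 0.47 for EVEN, 0.44 for ODD and 0.43 for LacZ, so the control pull-down shared a relation with arm GC. No absolute amounts were measured, so a smaller share and a real loss cannot be told apart.

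By library totals, the 9 miRNAs above LacZ and the input with both probe sets were also high in LacZ against the input. Their median log2 ratio was 1.09, at percentile 98.9 of expression-matched random lists, with 8 of 9 above 0 and 5 at least 2-fold. TMM factors lower every LacZ ratio to the input, taking the median of tested miRNAs from -0.44 to -1.04. That would put miR-409-3p (0.21) and miR-574-5p (0.04) below 0 and miR-877-5p (1.11) and miR-3187-3p (1.09) under 2-fold. The percentile does not change with scaling, but it counts miR-423-5p and miR-3184-3p, which are not 2 independent results. It goes with non-specific retention on beads or probes as part of the recovery of the 9. However, LacZ is the denominator of 1 of the 2 selections and the test was chosen after the values were seen. By library totals, the selection over the input removed none of the 9, and could not remove the 8 above 0. miR-21-5p is an exception, below the input in LacZ. Base composition stays open, with the median arm GC at percentile 81.7. Pairing with the probes also stays open: the energy of pairing with the antisense strand of exon 2 lay at percentile 11 among 200 shuffled strands, a test that replaced an energy difference at percentile 1.25, which had been seen first as 1 of 24 percentiles. Binding to circHIPK3 was not tested and remains open.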
